A study of Homo sapiens with 6 samples.

How the data were processed

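Per the labels, total RNA of CW-2 cells was labelled with Cy5 using the 3D-Gene miRNA labelling kit (Toray) and hybridised to 1-colour arrays, 1 per sample, with 3 control and 3 galectin-9 samples. The labels' extraction protocol speaks of serum and a reagent for liquid samples, although the samples are cells, and the names of the scanner columns carry the laser wavelength usual for Cy3 although the labels name Cy5; neither is resolved here. The authors deposited scanner output for each array, with the mean and median foreground intensity of each spot and the median and SD of its local background, on a linear scale and not normalized, per the file headers. The scanner and its software are not given in the sources used here. They also deposited a table of processed intensity values whose processing is not stated. Set against the scanner values, each of its columns ranks the probes exactly as that array's mean foreground does (Spearman rho 1). Its sorted columns differ from the first by at most 5.3. It thus holds quantile-normalized mean brightness on a linear scale, without subtraction of each spot's local background. Subtracting the same value from all spots of an array would keep the ranks and cannot be excluded. The table's column medians were 229.9 to 230. Its second highest value, 27392.7, is above those of the scanner files (8542.5 to 10970), so the target distribution came from elsewhere and is not given in the sources used here.

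Groups were taken from the treatment labels and replicate numbers from the titles. Each array had 3200 spots, among them 2019 human miRNA probes, 925 blanks and 24 negative controls. Mean foreground and median local background were corrected with normexp at offset 50 over all spots. Control spots were then left out, log2 was taken, and arrays were quantile-normalized over the 2019 miRNA probes. A probe counted as detected above the mean + 2 SD of the negative-control spots, 5% trimmed at each end; thresholds were 236.7 to 245.2. Tested were the 217 probes detected on all 3 arrays of at least 1 group, 176 of them on all 6 arrays. The test was limma's lmFit and eBayes with group as the only term and Benjamini-Hochberg adjustment; log2 differences are galectin-9 minus control. Probes in the same rank on every array have a change of exactly 0 after quantile normalization. No pair of arrays held identical values. Nothing states that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Quantile normalization removes any change shared by all miRNAs; without it the median of all tested miRNAs was -0.11.

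Design, lists, alternatives and the rule for named miRNAs were fixed before the data were examined. The rule took, with fewer than 12 miRNAs past the threshold in a direction, the 10 with the smallest unadjusted p in that direction, stated as not past it. It added 2 to 4 members of each list with the smallest p, and the 5 brightest miRNAs of the control arrays; the upper number, 4, was settled on after values had been seen. The plan allowed blank or negative-control spots for detection and did not name the foreground column. Negative controls and the mean foreground were chosen after the files were seen and before any group test; blank spots, the median foreground, scaling to spike controls, and setting each list against tested miRNAs of its own registry-number class (1000 or above, or below) are alternatives added after seeing the data. There were 11 miRNA lists and 3 lists of other cell types. Of 125 distinct miRNAs in them, 114 matched the array by name, 9 by registry identifier, and 2, miR-7704 and miR-8069, were not on the array. Lists with 3 or more tested members were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the 11 lists. The let-7 and bright-probe calls hold with the preset correlation and not with the estimated one.

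Same-numbered control and galectin-9 samples deviated together from their group means, with correlations of 0.293, 0.145 and 0.305 over the tested miRNAs, against -0.253 to 0.0264 for other pairs. By the rule that each pair must exceed 0.1, the numbers were taken to pair the samples, from the data and not from the labels. The counts of both fits were printed together with this check, and the decision followed the fixed rule. Deviations cancel within a group, so positive same-numbered values push the other pairs toward negative ones. Same-numbered arrays also had adjoining positions, so paired samples and a shared slide cannot be told apart. Array positions in the files were 1, 3 and 1 for control and 2, 4 and 2 for galectin-9 replicates 1 to 3. They imply at least 2 slides, with replicate 3 taken to lie on another; the slide itself is not given in the sources used here. Every control array had an odd position and every galectin-9 array an even one, so position and group cannot be told apart.

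The fit was tested on simulated data for the 217 probes, with independent probes and 20 simulations. In each simulation 20 probes were changed at each size together, and simulated values were not quantile-normalized. The fit recovered 72.8% of changes of 0.5, 97.2% of 1 and 100% of 2 on the log2 scale, with 4.5% false calls. So many changed probes ease the adjusted threshold, so these shares do not say what is recovered where few miRNAs change. A shifted list of 10 was called in 20 of 20 simulations and an unshifted one in 1. Alternatives covered background correction, offset, scaling, detection filter, the authors' table, the variance model, array weights, the replicate and slide blocks, the registry-number class and each sample left out in turn. Tools were R 4.3.3 with limma 3.58.1 and jsonlite 2.0.0, and Python 3.11.15 with matplotlib 3.10.9. Neighbouring miRNA genes were taken from RefSeq genes of GRCh38.p14; the files name no build, so no coordinates are given. Probe sequences were not used here, so GC content was not examined.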

Results

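The series measured microRNAs (miRNAs), short RNAs that repress their target messenger RNAs, in CW-2 cells, an established human colon cancer line. Cells treated with galectin-9, a beta-galactoside-binding lectin, were compared with control cells. The series as a whole asks how galectin-9 acts on colon cancer, and this comparison asks which miRNAs differed in the treated cells. There were 6 samples, 3 control and 3 galectin-9. Each was hybridised to a 3D-Gene array, a chip that reads each miRNA as the fluorescence of a spot. The sample titles give a time of 12 h, whereas the treatment protocol gives 24 h of culture followed by 48 h with galectin-9. The protocol lists 4 doses from 0.01 to 0.3 μM and assigns none of them to an array, so the exposure behind each value is not settled.

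Each array held 2019 human miRNA probes. The number detected above the negative-control spots was 417, 359 and 351 on control replicates 1 to 3 and 301, 242 and 311 on galectin-9 replicates 1 to 3. The means were 375.7 ± 36.0 in control and 284.7 ± 37.3 in galectin-9 samples (SD, n = 3 each; exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 samples allow). The difference was -91 with this threshold and -40 with a stricter one. With the threshold set on blank spots it was 71.3, within the spread of the samples (1280 ± 218 in control and 1351 ± 138 in galectin-9, SD, n = 3 each; exact two-sided permutation test, p = 0.7). Between 11 and 19 of the 24 negative-control spots per array passed the blank threshold. Over the 217 tested miRNAs, log2 values of control arrays correlated at 0.985 to 0.99 with each other, galectin-9 arrays at 0.977 to 0.989, and arrays of different groups at 0.969 to 0.984. Galectin-9 replicate 3 stood apart from the other galectin-9 arrays: on the first principal component (42.1% of the variance) it lay at 0.254, where replicates 1 and 2 lay at -2.65 and -1.8 and control arrays at 0.741 to 2.14. On the second (24.9%) it lay at -2.7 and the other 5 arrays at -0.153 to 1.4. The number of arrays limits the precision of every value.

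The brightest miRNA of the control arrays was miR-4454, followed by miR-1260b, miR-5100, miR-4286 and miR-4284. The miR-4454 spot was saturated on all 6 arrays, so its level is only bounded and no change can be read from it. Mean brightness of miR-1260b was 9400 ± 459 in control and 10132 ± 1377 in galectin-9 samples (SD, n = 3 each), and that of miR-5100 was 8251 ± 727 and 8058 ± 1453. These 3 probes held the same rank on every array, which sets their normalised change at 0. For miR-4286 the change was 0.18 (SE 0.159, limma adjusted p = 0.546) and did not pass. For miR-4284 it was 0, since quantile normalization gave both groups the same set of values. The change of miR-4284 was 0.127 after scaling to the median of detected probes and -0.0737 without normalization.

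No single miRNA passed the test between galectin-9 and control cells. With limma and Benjamini-Hochberg adjustment, 0 of 217 miRNAs were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.075. At an unadjusted p under 0.05 there were 44, of which 17 were higher and 27 lower, against 10.9 expected by chance. With the replicate number as a block these were 27 higher and 29 lower, and with the inferred slide as a block 29 and 26. They were 28 and 31 without galectin-9 replicate 3 and 15 and 17 without control replicate 2. Among the 176 miRNAs detected on all 6 arrays they were 17 and 19. The lean toward lower values thus depended on the fit and on the detection filter. It was wider under other scalings, with 0 higher and 35 lower at the 75th percentile, 0 and 33 without normalization and 0 and 10 with spike scaling, but 15 and 14 after median scaling. At an adjusted p under 0.1 there were 1 higher and 4 lower. That count of 5 went to 0 without any 1 of control replicates 1, 2 or 3 or galectin-9 replicates 1 or 2, and to 14 without galectin-9 replicate 3. In 49 of the 217 (22.6%) all galectin-9 values lay on one side of all control values, where chance gives 10%. Other ways of fitting or scaling the same values gave between 0 and 6 calls. The variance model also took in miR-4454, miR-1260b and miR-5100, whose SD is 0 in both groups because their ranks are fixed. Whether this raised the p-values of the other miRNAs was not tested. With limma's eBayes set to trend and robust there were 1 higher and 3 lower, at a smallest adjusted p of 0.0107.

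Among miRNAs with higher values in galectin-9 samples, the smallest p belonged to miR-15b-5p, which with miR-16-5p shares a seed that targets BCL2 and several cyclins. Its level was 1.42-fold that of control (log2 0.50, SE 0.089, adjusted p = 0.075, n = 3 per group), and that of miR-16-5p was 1.38-fold (log2 0.47, SE 0.0972, adjusted p = 0.125). Next came let-7b-5p, of the tumour-suppressive let-7 family, at log2 0.36 (SE 0.0795, adjusted p = 0.135). Without between-array normalization these 3 values were 0.29, 0.22 and 0.06. The values of miR-191-5p and miR-425-5p, which are cut from one primary transcript, were 0.30 and 0.17, and miR-425-5p lay at -0.04 without between-array normalization and at -0.01 after scaling to the 75th percentile. The 10 smallest p-values in this direction also took in miR-26b-5p (0.39), let-7e-5p (0.30), miR-324-3p (0.24), miR-203a (0.24), a miRNA of epithelial differentiation, and miR-1233-1-5p (0.23). Adjusted p for these and for miR-191-5p and miR-425-5p ran from 0.14 to 0.206, and none passed the threshold. Without normalization miR-191-5p, miR-203a and miR-1233-1-5p were at 0.05 each, let-7e-5p at 0.12, miR-324-3p at 0.17 and miR-26b-5p at 0.21.

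Among miRNAs with lower values in galectin-9 samples, 8 of the 10 with the smallest p have registry numbers of 1000 or above. The lowest p was that of miR-1237-5p, 1.55-fold lower than in control (log2 -0.63, SE 0.0949, adjusted p = 0.075, n = 3 per group). At the same adjusted p lay miR-3665 (-0.48, SE 0.087), miR-4505 (-0.47, SE 0.0751) and miR-4327 (-0.40, SE 0.0725). The miR-4327 probe was not above the detection threshold on any galectin-9 array, so its level there is a bound. Its fall was estimated at 1.29-fold or more in the main setting. The same holds for miR-4730, at 1.2-fold or more (limma adjusted p = 0.14). Both were tested only because every control array detected them. These estimates leave out the spread between samples and depend on the normalization. After median scaling the log2 differences were -0.28 for miR-4327 and -0.169 for miR-4730. Such bounds set the mean of the brighter group against the lowest detected signal of each dimmer array, or the probe's own value where that was higher. The remaining lower values were miR-6132 (-0.51), miR-192-3p (-0.38), miR-1228-5p (-0.31), miR-1469 (-0.25) and miR-744-5p (-0.21), with adjusted p from 0.135 to 0.189. Of these, miR-192-3p and miR-1469 were detected on 1 of the 3 galectin-9 arrays. They too were tested only because every control array detected them, and after median scaling they were at -0.19 and -0.0841.

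**Figure D1:**
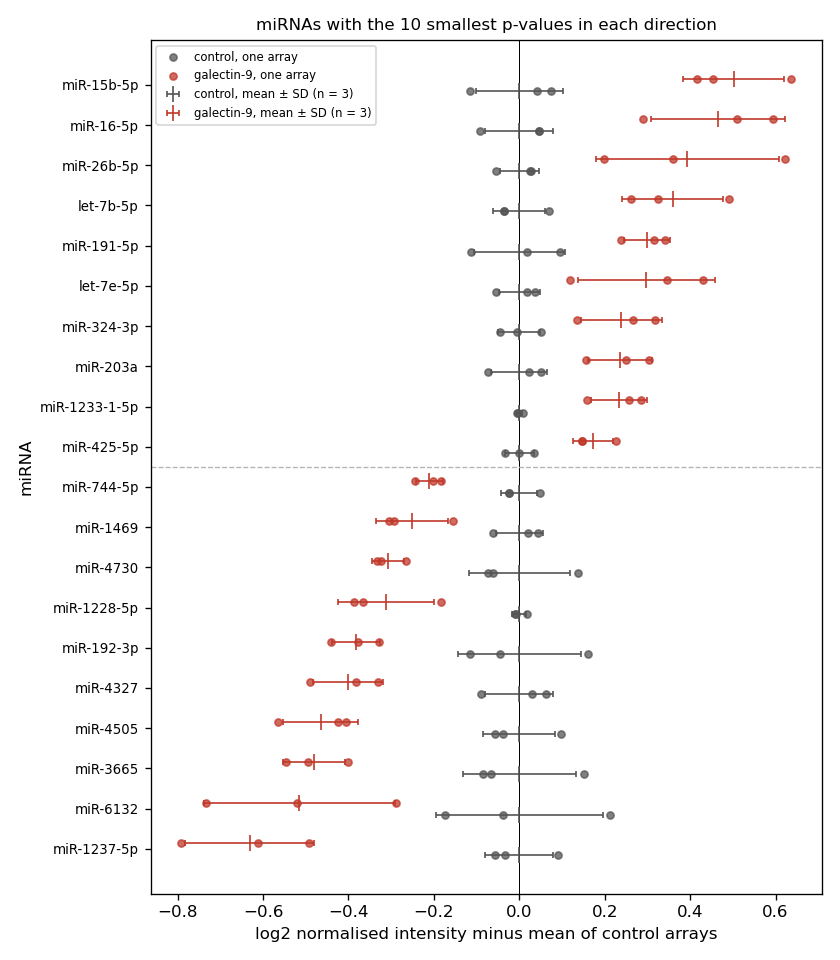
Normalised log2 intensity of the 10 higher and 10 lower miRNAs with the smallest p-values, each minus the mean of its control arrays (x axis), with miRNAs on the y axis; points are single arrays, crosses with bars are mean ± SD (n = 3 per group). Galectin-9 and control arrays do not overlap for any of the 20, which were picked for small p-values, yet the smallest adjusted p was 0.075; miR-425-5p was at -0.04 without normalization and -0.01 after scaling to the 75th percentile.

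The let-7 family, whose seed represses growth-promoting targets such as RAS and MYC, rose as a list in galectin-9 samples when set against all tested miRNAs. The mean log2 difference over its 9 tested members was 0.19, with 8 higher and 1 lower, and this mean stayed above 0 under each scaling tried, at 0.00504 without normalization. The list passed the camera test with a preset correlation (adjusted p = 0.0446 over 11 lists), but adjusted p = 0.262 with an estimated correlation; fry, which asks whether the members move one way on balance, gave an adjusted p of 0.0423. Over all miRNAs 0 members passed, and adjusted over the list alone 1 did, let-7b-5p (adjusted p = 0.0408). The values of let-7e-5p, let-7d-5p and let-7g-5p were 0.30, 0.17 and 0.16 and did not pass, and let-7c was at -0.09. Members differ by few bases, and whether their probes share signal was not tested. The mean was 0.20 in replicates 1 and 2 and 0.17 in replicate 3. Most tested miRNAs with registry numbers below 1000 were also higher: the 129 outside this family had a mean of 0.06, and against them alone the list did not pass (adjusted p = 0.182). The call was lost in 13 of 23 alternatives, with adjusted p from 0.00422 to 0.182 over all of them, among them without galectin-9 replicate 1 (0.0952) or 2 (0.0534).

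The list of probes that tend to be bright on such arrays with any sample, described when it was fixed as rich in G and C at the 5-prime end, fell in galectin-9 samples against all tested miRNAs, but no further than other miRNAs of its registry-number class. Its 22 tested members had a mean log2 difference of -0.14, with 2 higher, 17 lower and 3 at 0, and the mean was below 0 under each scaling tried. All have registry numbers of 1000 or above, and the other 57 tested miRNAs of that class had a mean of -0.16, with 44 lower; against them alone the list did not pass (adjusted p = 0.738). The camera test gave adjusted p = 0.0446 with the preset correlation and adjusted p = 0.262 with an estimated correlation, and fry gave an adjusted p of 0.0715. No member passed over all miRNAs, and adjusted over the list alone 1 did, miR-3665 (adjusted p = 0.038). Of the others, miR-6090 was at -0.40, miR-4508 at -0.40 and miR-4466 at -0.18. The 3 members at 0 were the saturated miR-4454, miR-1260b and miR-5100, fixed there by their ranks. After median scaling they were at 0.195, 0.303 and 0.155, where the list mean was -0.106. Without normalization they were at -0.00554, 0.102 and -0.0463, where the list mean was -0.307. In the main setting the list mean was -0.16 in replicates 1 and 2 and -0.11 in replicate 3. The call was lost in 12 of 23 alternatives (adjusted p from 0.0043 to 0.738 over all of them). Among the 12 were the fits without control replicate 1 (0.0668), 2 (0.0544) or 3 (0.223) and without galectin-9 replicate 1 (0.159) or 2 (0.0534). Without galectin-9 replicate 3 the call held, with a mean of -0.189, or -0.229 against the median of all tested miRNAs.

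The miR-15/16 family did not pass as a list. Of its 3 tested members, miR-15b-5p and miR-16-5p were higher and miR-15a-5p was at -0.03, with a list mean of 0.31 (0.09 without normalization, 0.12 at the 75th percentile; adjusted p = 0.0532; adjusted p = 0.262 with an estimated correlation). Adjusted over the list alone, 2 members passed, miR-15b-5p (adjusted p = 0.00469) and miR-16-5p (adjusted p = 0.00519), while over all miRNAs 0 did. With the inferred slide as a block the list passed (adjusted p = 0.0444), as it did without control replicate 1 (0.0443) or 2 (0.0338), in a range of 0.0237 to 0.182 over all alternatives. Its mean was 0.30 in replicates 1 and 2 and 0.34 in replicate 3.

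All 7 tested members of the miR-29 and miR-30 families, which target matrix and differentiation genes, had higher values, with a mean of 0.18 (-0.000498 without normalization) that did not pass (adjusted p = 0.0532; adjusted p = 0.262 with an estimated correlation). Examples were miR-29b-3p at 0.37, miR-30c-5p at 0.20, miR-29c-3p at 0.19 and miR-29a-3p at 0.14. The miR-23/27/24 clusters had 5 of 5 higher, with a mean of 0.18 that stayed above 0 under each scaling but came to 5.01e-05 without normalization (adjusted p = 0.0615; adjusted p = 0.262 with an estimated correlation). Among them miR-27b-3p was at 0.26, miR-24-3p at 0.26, miR-23b-3p at 0.17 and miR-23a-3p at 0.12. With the inferred slide as a block both lists passed, at adjusted p = 0.0316 and 0.0444. Without control replicate 2 both also passed (0.0125 each), and the miR-29 and miR-30 list passed without control replicate 1 (0.0443) or galectin-9 replicate 3 (0.046). Over all alternatives their adjusted p ran from 0.0043 to 0.306 and from 0.0125 to 0.306. The means in replicates 1 and 2 and in replicate 3 were 0.15 and 0.25 for the former list and 0.16 and 0.22 for the latter.

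The p53-induced list, which holds miRNAs transcribed downstream of p53, had 4 of 5 members higher and a mean of 0.17 (-0.03 without normalization), and did not pass (adjusted p = 0.13). Its values included miR-215 at 0.32, miR-192-5p at 0.22, miR-34a-5p at 0.18 and miR-107 at 0.16. The intestinal epithelium list shares 3 members with it and had 4 of 7 higher, with a mean of 0.13 (-0.06 without normalization, -0.03 at the 75th percentile; adjusted p = 0.137); miR-375 was at 0.19 and miR-203a at 0.24. In the inflammation and stress list all 4 tested members were higher, with a mean of 0.14 (-0.02 without normalization; adjusted p = 0.157), among them the hypoxia-induced miR-210 at 0.24 and the NF-kB-induced miR-155-5p at 0.21, with miR-125a-5p at 0.11 and miR-146a-5p at 0.01. For these 3 lists the adjusted p with an estimated correlation was 0.262. The p53 mean was 0.23 in replicates 1 and 2 and 0.04 in replicate 3, and the inflammation mean 0.16 and 0.10. Against the median of all tested miRNAs, the intestinal mean was 0.0488 without galectin-9 replicate 1, and without control replicate 3, which brings the tested members to 6, the inflammation mean was 0.0546.

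Of miRNAs widely reported as raised in colorectal tumours, 5 of 6 were higher, with a mean of 0.11 (-0.05 without normalization, -0.02 at the 75th percentile; adjusted p = 0.16). The values were 0.23 for miR-182-5p, 0.21 for miR-222-3p, 0.14 for miR-224-5p and -0.06 for miR-96-5p. The MYC-driven polycistron that starts with miR-17, taken with its paralogous clusters, had 11 of 12 members higher, with a mean of 0.10 (-0.07 without normalization, -0.04 at the 75th percentile; adjusted p = 0.16). Their smallest p-values were those of miR-19b-3p at -0.16, miR-20b-5p at 0.21, miR-18a-5p at 0.29 and miR-93-5p at 0.14. The miR-200 family of epithelial identity had 3 of 5 higher and a mean of 0.05 (-0.07 without normalization, -0.04 at the 75th percentile; adjusted p = 0.571), with miR-429 at 0.16, miR-141-3p at 0.13, miR-200b-3p at 0.02 and miR-200c-3p at -0.06. With an estimated correlation the adjusted p was 0.381 for the first 2 of these lists and 0.684 for the miR-200 family. Against the median of all tested miRNAs, the colorectal mean was 0.069 without control replicate 2, with 7 members tested, and 0.0604 without galectin-9 replicate 1. On the same measure the miR-17 cluster mean was 0.0576 without galectin-9 replicate 2. Also against that median, the miR-200 mean was -0.0399 without galectin-9 replicate 1, 0.0303 without replicate 2 and 0.0938 without replicate 3. It was 0.0854 without control replicate 3. Not set against that median, the means of the colorectal, miR-17 cluster, miR-200 and intestinal lists in replicate 3 alone were -0.08, -0.06, -0.18 and -0.04. In replicates 1 and 2 they were 0.20, 0.17, 0.16 and 0.21. None of the lists without a call had a member that passed over all miRNAs, and of them only the miR-15/16 family had members that passed when adjusted over the list alone.

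**Figure D2:**
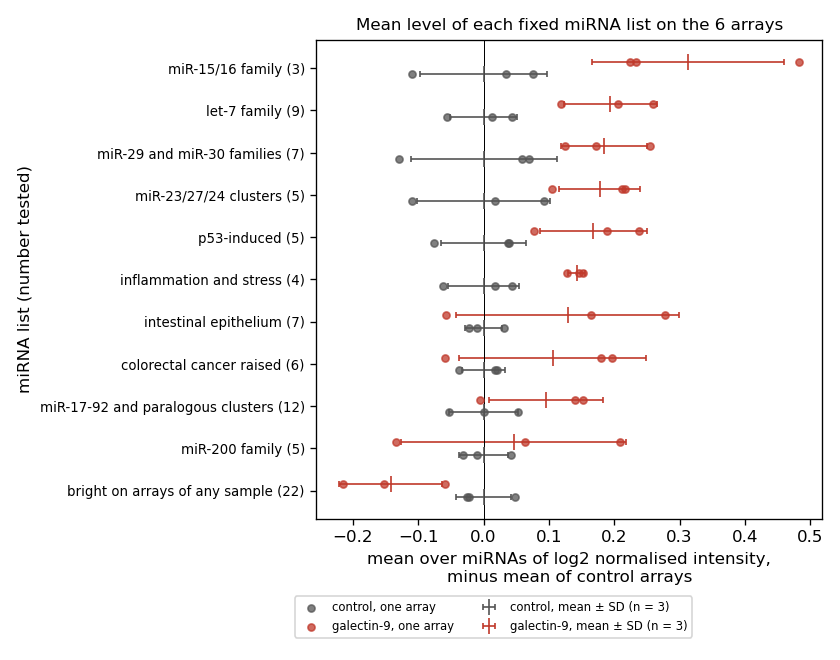
Mean normalised log2 intensity over the tested members of each miRNA list on each array, minus the mean of the control arrays (x axis), with lists and their number of tested members on the y axis; points are single arrays, crosses with bars are mean ± SD (n = 3 per group). The let-7 means of the galectin-9 arrays lie at 0.12 to 0.26; without between-array normalization the changes of the miR-17 cluster, miR-200, p53, intestinal, colorectal, miR-29 and miR-30, and inflammation lists lie below 0.

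Markers of other cell types were near or below detection. Of 8 miRNAs of blood cells and serum 1 was tested, miR-223-3p at -0.00125, which was detected on 1 of 3 galectin-9 arrays. Of 7 miRNAs of fibroblasts, smooth muscle and endothelium 2 were tested, miR-10b-5p at 0.07 and miR-126-3p at 0.05, and of 7 of muscle and nerve 1 was, miR-128 at 0.04. None of these passed, and the lists held too few tested members for a list test.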

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

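The array also carries 22 probes with plain S-Probe numbers in place of a miRNA name. They enter no comparison of the report, and what they detect is not given in the sources used here. With arrays scaled to the median of detected miRNA probes, 5 of the 11 detected on all 6 arrays had every galectin-9 value above every control value, where chance gives 5% of probes. The log2 differences were 0.313 for S-Probe1006, 0.362 for S-Probe1008, 0.308 for S-Probe1010, 0.304 for S-Probe1011 and 0.258 for S-Probe1012 (n = 3 per group). On that scale the median of the tested miRNAs was 0.091, a common shift that the 5% does not allow for. In the main setting 22.6% of tested miRNAs were separated in either direction, where chance gives 10%. The share of miRNAs separated upward on the median scale was not examined. Without normalization the differences of these 5 probes were 0.112, 0.161, 0.107, 0.103 and 0.0569.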

How the results depend on the processing

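Median foreground, detection on blank spots, scaling to spike controls and setting lists against their registry-number class were chosen after seeing the data; the other alternatives were planned. Values are relative to the median of all tested miRNAs, and unless a construction is named the cause was not tested. Depth limits the list of tested miRNAs: a miRNA near the negative controls is measured as a bound. The 20 miRNAs with the smallest p-values passed in 14 of their 436 values from 16 alternatives and 6 fits with a sample left out. None of these values changed direction. Their groups do not overlap, so leaving out a sample had little room to turn it, although the arrays were normalized anew each time.

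No miRNA passed in the main setting or in 12 of the 16 alternatives, nor with any sample left out. Scaling to the median of detected probes gave 0 higher and 2 lower, scaling to the 75th percentile 0 and 6, eBayes with trend and robust on 1 and 3, and array weights 2 and 4. A threshold of adjusted p under 0.1 gave 1 and 4, and unadjusted p under 0.05 gave 17 and 27. That last split was 15 to 14 after median scaling and 0 to 35 at the 75th percentile. It was 0 to 33 without normalization and 0 to 10 with spike scaling. These scalings move all miRNAs together. The split was 27 to 29 with the replicate block, 29 to 26 with the slide block and 17 to 19 among miRNAs detected on all 6 arrays. It was 28 to 31 without galectin-9 replicate 3 and 15 to 17 without control replicate 2. The count at an adjusted p under 0.1, 5 in all, was 14 without galectin-9 replicate 3, 0 without each other sample and 17 with array weights. With the replicate block there were 0 higher and 0 lower (smallest adjusted p 0.0842), and the pairing of the replicates changed no call, the let-7 (adjusted p = 0.0118) and bright-probe (0.0338) lists included. The number detected differed by -40 at 3 SD, by 71.3 with the blank threshold (exact permutation p = 0.7), and by -104 to -69.7 with a sample left out.

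The let-7 call was lost without background correction (0.14), with blank subtraction (0.25), with offset 16 (0.22), under the 3 other scalings and without normalization (0.115 each, adjusted p 0.114 to 0.168), with probes detected on all 6 arrays (0.16, 1 member fewer), with the authors' table (0.20), with median foreground (0.17) and against its registry-number class (0.118); its adjusted p ran from 0.00422 to 0.182. With a sample left out it was 0.16 to 0.23. The bright-probe call was lost without background correction (-0.10), with blank subtraction (-0.19), offset 16 (-0.16), the authors' table (-0.17), trend and robust eBayes (-0.14) and median foreground (-0.15), and against its registry-number class, where the value turned to 0.00303; its adjusted p ran from 0.0043 to 0.738. That class was lower as a whole, so the loss against it shows only that the list shared the shift of its class. What moved the class is not settled, and the cause of the other losses was not tested. With a sample left out the mean of the bright-probe list was -0.23 to -0.10.

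Calls were gained with all probes tested by miR-15/16 (0.16), miR-29 and miR-30 (0.20) and miR-23/27/24 (0.18), with the slide block by the same lists (0.31, 0.18 and 0.18), and with detection on blank spots by miR-29 and miR-30 (0.18). With a sample left out these lists were 0.22 to 0.36, 0.14 to 0.24 and 0.14 to 0.25. The miR-200 list was -0.0399 to 0.0938, below 0 without galectin-9 replicate 1, and -0.0304 against its registry-number class.

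Of 44 other named miRNAs 10 changed sign in at least 1 of their values, all with small changes. For miR-200b-3p the value was -0.00575 without background correction, -0.00942 with blank subtraction, -0.0278 under the 3 other scalings and without normalization, -0.0179 with probes detected on all 6 arrays, -0.0157 in the authors' table and -0.0252 with median foreground. For miR-146a-5p these were, in the same order, -0.0497, -0.179, -0.0135, -0.0232, -0.127 and -0.0344, and -0.00168 with detection on blank spots. For miR-223-3p they were 0.0462 under those scalings, 0.0304 with array weights and 0.00165 with median foreground. Median foreground turned miR-125a-5p to -0.0127, miR-10b-5p to -0.0471 and miR-126-3p to -0.0361. With a sample left out the ranges were -0.19 to 0.0435 for miR-200c-3p, -0.025 to 0.058 for miR-200b-3p, -0.15 to 0.078 for miR-15a-5p, -0.16 to 0.0502 for miR-96-5p, -0.000783 to 0.22 for miR-125a-5p, -0.048 to 0.044 for miR-146a-5p, -0.10 to 0.057 for miR-223-3p, -0.0298 to 0.19 for miR-10b-5p, -0.027 to 0.13 for miR-126-3p and -0.11 to 0.19 for miR-128.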

Other observations

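The tests of normalization and of galectin-9 for the registry-number pattern, of the detection threshold, and of the splits for the count at an adjusted p under 0.05 were chosen after the result was seen. The single arms and neighbours named below were also picked after their values were seen.

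Of 7 precursors with both arms tested, the miR-192 precursor, abundant in gut epithelium, had its arms furthest apart. The guide arm miR-192-5p was at 0.217 (unadjusted p = 0.211, limma) and miR-192-3p at -0.382 (unadjusted p = 0.00553), or 0.177 and -0.19 after median scaling. The miR-192-3p probe was detected on 1 of 3 galectin-9 arrays and was tested only because every control array detected it. For miR-191 the values were 0.298 for the 5p arm and -0.0797 for the 3p arm, and for miR-324 they were 0.239 for the 3p arm and 0.0362 for the 5p arm. Differences between arms were not tested. Many miRNA genes lie in clusters that are transcribed together, such as let-7e with miR-125a and miR-99b. Their values were 0.298, 0.107 and -0.139, and those of miR-182-5p and miR-96-5p were 0.234 and -0.0618.

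Of the 217 tested miRNAs 209 (96.3%) were placed on RefSeq genes, and 77 pairs lay within 10000 bases. Shared transcription may bring neighbours closer together, but their mean absolute difference was 0.171 against 0.188 for permuted pairs (permutation test, 100000 permutations, one-sided, p = 0.247). Among 66 pairs of different miRNA number it was 0.181 against 0.189 (permutation test, p = 0.409), which says nothing of similar sequence, since pairs such as miR-15b and miR-16 or let-7f and miR-98 share a seed. The prediction written for this test took a p above the threshold as evidence against shared transcription, which was too strong, since such a p does not show that neighbours move apart; shared transcription and similar sequence both stay open. The placement on genes was redone after a first one covered too few miRNAs, with its p already seen.

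In galectin-9 samples, miRNAs numbered 1000 or above in the miRNA registry, which were named later and are often less well documented, tended to be lower, and earlier ones higher. Of 79 late-numbered miRNAs 61 (77.2%) were lower, with a median of -0.145, and of 138 early-numbered 93 (67.4%) were higher, with a median of 0.0763, a gap of -0.222 (bootstrap interval over probes, which leaves out the spread between samples, -0.292 to -0.159). The values argue against quantile normalization (gap -0.235 without it), a trend with brightness (-0.236 within bins of brightness), uneven signal over the array (-0.218 among probes of one block) and a steady gradient along the slide (0.0283 between arrays of one group 2 positions apart, where a gradient would give -0.443). Galectin-9 arrays of the same position differed by 0.138 in this gap and control arrays by 0.0296; it was -0.246, -0.251 and -0.179 in replicates 1 to 3, and 1 of the 10 splits of the 6 arrays, the real one, gave a gap as large (highest other in size 0.152), too few splits for a share under 0.05. Galectin-9 may be the source, but odd against even array position, RNA input or quality and the GC content of the probes were not tested and stay open, and position cannot be told apart from group. The gap was not recomputed among miRNAs detected on all 6 arrays, so a part played by the detection filter also stays open.

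The lower number of miRNAs detected in galectin-9 samples, -91 on average, may come from where the threshold lies. It was -40 at 3 SD, where the groups still did not overlap, and 71.3 with the threshold on blank spots, where the groups overlapped (exact permutation test, p = 0.7); at that threshold 11 to 19 of the 24 negative-control spots also passed. The last value is not distinguishable from 0, so the separation of the groups, and not an opposite direction, depends on the choice of background spots; galectin-9 as the cause was not tested and stays open.

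With 3 against 3 samples there are 10 splits, too few for a share under 0.05. At an adjusted p under 0.05, all 10 splits gave 0 miRNAs, the real one included. At an unadjusted p under 0.05 the real split gave 44 and the highest other 20, and 1 split, the real one, gave as many. The let-7 mean was 0.194 against 0.155 in the highest other split, and that of the bright-probe list was -0.142 against 0.131 in size.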
